A study of Mus musculus with 8 samples.

How the data were processed

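Ribosome profiling and input RNA were measured in B16 mouse melanoma cells, WT and Mettl5 KO, in 8 libraries, 2 per group. Per the labels, cells were treated with cycloheximide, which halts ribosomes on mRNA, and lysed in a polysome buffer, and ribosomal RNA was depleted. The labels name both a small RNA kit and a ribosome profiling kit for the libraries, and which was used is not settled by the sources used here. The labels give the input both as polyadenylated RNA and as RNA depleted of ribosomal RNA, and the kind of input RNA is not settled by the sources used here. Bowtie (no version given) and the mouse build mm10 are named per the submitters' processing notes. The counter, the gene annotation, read length filters, the treatment of reads with several matches and strand are not given in the sources used here, so reads shared by near-identical genes or pseudogenes could have been split or lost.

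The authors deposited a single table with 1 row per gene (10453 genes) and 8 columns of normalized read counts, whose unit is treated here as signal. From the values, each column holds whole multiples of what 1 read is worth, between 0.307 and 0.483 in input and between 2.12 and 2.95 in footprint libraries, and 100% of the values in every library came out whole within 0.001 of a read. The reads recovered in this way were 14402586 and 11927567 (WT input), 18823632 and 14835551 (KO input), 3098930 and 2862517 (WT footprints), and 2344656 and 2279456 (KO footprints). These sums cover only listed genes, which all have at least 1 read in every library, and 0 columns of samples were left unmapped. The authors also deposited a log2 fold change of translational efficiency, its p-value and adjusted p-value, and a call (Up, Down or neither) per gene, per the file headers. The test behind them is not named in the sources used here. By recomputation, DESeq2's model with genotype, kind of library and their interaction on the recovered reads gave log2 fold changes that differed by over 0.001 from the authors' deposited values in 0 genes, and 1824 genes to which that fit gives no adjusted p (NA) are the same 1824 with an adjusted p of exactly 1 in the authors' deposited table. The smallest absolute log2 fold change of the authors' deposited Up calls was 0.585 and of their Down calls 0.581. Gene symbols are those of the table. 16 symbols that a spreadsheet had turned into dates were restored from the gene ID, and 10452 of the IDs matched the name table.

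Before the data were examined, edgeR on counts had been chosen as the main test, with limma for normalized values. Since the table held normalized values, the main test was limma-trend (limma 3.58.1, R 4.3.3) on log2(value + 1), for genes with a mean value of at least 1, and a fold change is on that scale, which understates the change of low genes. Input libraries and footprint libraries were each fitted alone (2 against 2). Translational efficiency was the interaction of genotype and kind of library over all 8 libraries, for genes that passed the filter in both kinds. That fit gave each gene 1 variance, moderated by its mean level over both kinds of library, although footprint libraries varied more. Its errors and p-values can therefore be too small for genes with few footprint reads for their input. P-values are two-sided and Benjamini-Hochberg adjusted, with a threshold of 0.05, and errors are standard errors (SE) or standard deviations (SD). Gene lists (27, of which 25 had at least 5 measured members) were fixed before the data were examined and tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. With an estimated correlation, camera uses only the residual degrees of freedom of the fit, which are few with 2 against 2 libraries. Not passing there can therefore reflect the number of libraries and not correlation between genes. By a rule also fixed before the files were seen, the named genes are Mettl5 and its partner, then the 10 largest and 10 smallest log2 fold changes per comparison among genes past the threshold whose libraries do not overlap between genotypes (skipping predicted genes), and up to 4 members of each list. An item under this rule is not reported here. Genes named outside this rule are Atf4, Ddit4, 2 histone genes and the replication-independent histones and Gapdh of the closing section, and were chosen after their values were seen, as were genes of the rule set in a comparison other than their own. edgeR 4.0.16 (TMM scaling, quasi-likelihood test) and DESeq2 1.42.0 on the recovered reads, and a minimum of 20 reads in every library, were alternatives chosen after seeing the data. edgeR called 3802 genes in input, 1473 in footprints and 1343 in translational efficiency. DESeq2 called 1721, 460 and 1023. It gave an adjusted p to only 5184 of 10453 genes in footprints and 8629 in translational efficiency, and genes without one could not be called. Other alternatives were a replicate block, centring on the median gene, other filters, a pseudocount of 0.1, limma without the trend, both kinds of library fitted together, a ratio per replicate number, and each library left out in turn. Calls within lists were counted again only with edgeR, DESeq2, limma without the trend, both kinds fitted together (input and footprints) and each library left out.

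Libraries of a group differed by slightly more than independent counting would give. Over genes with at least 100 reads in the pair, the chi-square of the reads divided by its degrees of freedom was 1.1 for WT input, 1.22 for KO input, 1.16 for WT footprints and 1.12 for KO footprints (largest p 3.95e-11). At the median footprint depth of 71 to 98 reads per gene, small changes are seen poorly. On data simulated from the libraries' means, depths and dispersions, with 50 genes changed at each size, the test of input found 88% of genes changed 1.5-fold and 98% of those changed 2-fold, with 4 false calls among 10241 unchanged genes. For footprints it found 38% and 80%, with 4 false calls among 10252, and for translational efficiency 40% and 54%, with 7 among 10237. Coordinates come from the RefSeq annotation of GRCm38, the assembly behind mm10. Figures were drawn with matplotlib 3.10.9.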

Results

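The series measured RNA and ribosome footprints in B16 cells, a mouse melanoma line that makes pigment. Cells labelled wild type (WT) were compared with cells in which Mettl5 had been targeted by CRISPR/Cas9 (labelled KO). METTL5 is the methyltransferase that places m6A on 18S rRNA of the small ribosomal subunit, and the title of the series links it to the expression of stress response genes. Each of the 4 groups (WT input RNA, KO input RNA, WT footprints and KO footprints) had 2 libraries. Input libraries held between 11927567 and 18823632 recovered reads, and footprint libraries between 2279456 and 3098930. The median gene had between 504 and 790 reads in an input library and between 71 and 98 in a footprint library. All 10453 listed genes had at least 1 read in every library, so genes silent in a library were not analysed here. Footprint changes were therefore measured on far fewer reads than input changes, and in the KO footprint libraries 13.0% and 13.9% of genes had under 10 reads. The labels do not say that the replicates of a group were separate cultures or clones, so p-values measure only the spread between these libraries, which may be technical. That spread was only slightly above counting noise (chi-square over degrees of freedom between 1.1 and 1.22). Very small p-values therefore need not hold for separately grown cells or other clones of the same genotype.

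Mettl5 itself (ENSMUSG00000051730.15, GRCm38/mm10, chromosome 2, start 69871195, end 69886634) was 1.32-fold lower in the input of the libraries labelled KO. Its normalized reads were 112 ± 2.51 (SD, n = 2) in WT and 85.7 ± 14.1 in KO (log2 fold change -0.40 ± 0.10 (SE), adjusted p = 0.00162). Its footprints were not lower: 102 ± 15.2 in WT and 110.4 ± 2.61 in KO (log2 fold change 0.12 ± 0.23, adjusted p = 0.812), from 92 and 76 reads summed over the libraries of each group, and the sign turned to -0.029 without WT footprint replicate 1. Counts per gene do not show a small insertion or deletion, so they do not check the edit, and KO below stands for the libraries labelled KO. Trmt112, the known partner of METTL5, was not analysed here.

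**Figure D1:**
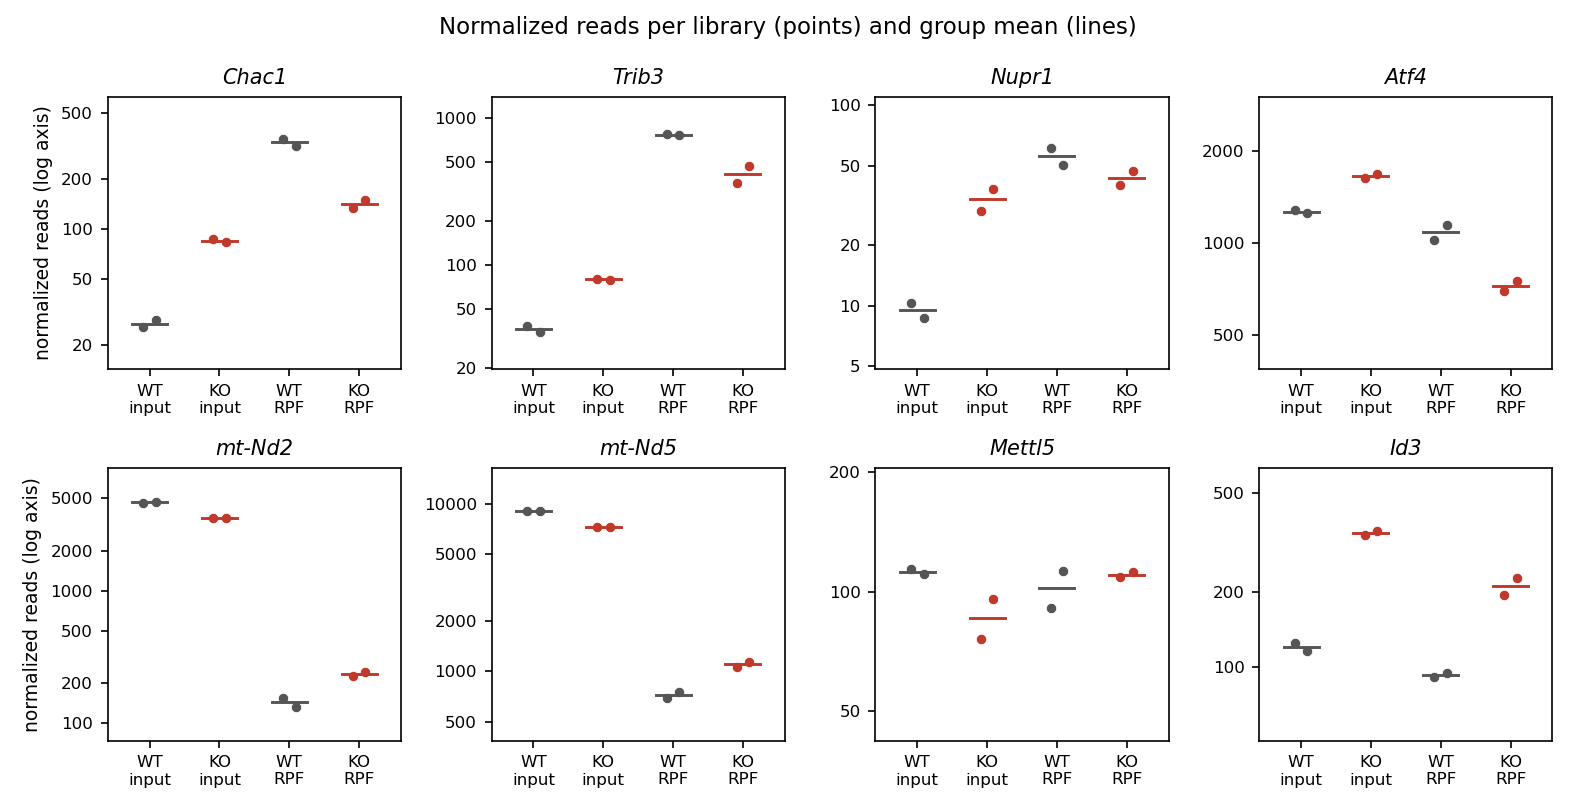
Normalized reads (log axis) of 8 genes in each of the 8 libraries, as points, with the mean of each group of 2 libraries as a line. Chac1, Trib3, Nupr1 and Atf4 lay higher in KO than in WT input and lower in KO than in WT footprints (for Nupr1 the footprint difference did not pass the test), mt-Nd2 and mt-Nd5 the other way round, and Id3 was higher in KO in both.

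In input RNA, the comparison of KO with WT asks which mRNA levels differ between the genotypes. In the integrated stress response the transcription factor ATF4 raises genes of amino acid supply and redox balance, and most of its listed targets were higher in KO. Of 33 integrated stress response genes, 29 rose and 0 fell (30 and 0 adjusted over the list alone), with a median log2 change of 0.37. For integrated stress response genes, camera adjusted p = 2.26e-26, and adjusted p = 0.142 with an estimated correlation. Nupr1, a stress-induced nuclear protein, rose 3.31-fold, from 9.53 ± 1.19 to 34 ± 6.04 normalized reads (SD, n = 2; log2 fold change 1.73 ± 0.21 (SE), adjusted p = 9.9e-09). Chac1, which degrades glutathione, rose 3.1-fold (log2 fold change 1.63 ± 0.13 (SE), adjusted p = 3.48e-13). Gpt2, the mitochondrial alanine aminotransferase, rose 2.38-fold (adjusted p = 9.75e-22). The pseudokinase gene Trib3 rose by 1.09 on the log2 scale (adjusted p = 2.23e-09). All 7 measured genes encoded in the mitochondrial genome fell, while 54 of 71 nuclear-encoded genes of oxidative phosphorylation rose. Neither list passed with an estimated correlation (adjusted p = 0.266 and adjusted p = 0.142).

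Among the single genes with the largest increase, beside Nupr1 and Chac1, were Id3, an inhibitor of basic helix-loop-helix transcription factors (120.4 ± 5.75 to 345 ± 8.34 normalized reads, log2 fold change 1.51 ± 0.064 (SE), adjusted p = 1.79e-21), the proteoglycan gene Bcan (1.48) and the cadherin gene Cdh13 (1.29). Col11a1 (2.05), Proser2 (1.72), Cyp4v3 (1.41) and Mfsd2a (1.32) rose from low levels, Col11a1 from 6 reads over both WT libraries to 48 in KO. The largest decreases were those of Tmeff1 (log2 fold change -2.32 ± 0.36 (SE), adjusted p = 1.76e-06), from 50 summed reads to 8, and of Itga2, which encodes integrin alpha 2 (-1.99). Log2 fold changes between -1.71 and -1.42 were those of Mgst1, a microsomal glutathione transferase, Shroom1, Pde3a, Rab17, Cyp26b1, which inactivates retinoic acid, Rhox5, Pard6g and Capn6. Capn6 was the most abundant of these, at 145 ± 2.15 normalized reads in WT and 54 ± 7.81 in KO.

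Of 71 nuclear-encoded oxidative phosphorylation genes, 54 rose and 0 fell (55 and 0 adjusted over the list alone), with a median log2 change of 0.19. For nuclear-encoded oxidative phosphorylation genes, camera adjusted p = 1e-18, and adjusted p = 0.142 with an estimated correlation. Ndufb7, a subunit of complex I, rose by 0.64. Of 7 mitochondrially encoded genes, 0 rose and 7 fell (0 and 7 adjusted over the list alone), with a median log2 change of -0.26. For mitochondrially encoded genes, camera adjusted p = 5.79e-14, and adjusted p = 0.266 with an estimated correlation. mt-Nd6 fell by 0.65 and mt-Nd2 by 0.39 on the log2 scale. Of 59 cytosolic ribosomal proteins, 56 rose and 1 fell (56 and 1 adjusted over the list alone), with a median log2 change of 0.15. For cytosolic ribosomal proteins, camera adjusted p = 1.43e-36, and adjusted p = 0.266 with an estimated correlation. Rplp2 (0.31), Rplp1 (0.30), Rps12 (0.29) and Rpl41 (0.26) changed most. Of 26 unfolded protein response genes, 18 rose and 3 fell (18 and 3 adjusted over the list alone), with a median log2 change of 0.17. For unfolded protein response genes, camera adjusted p = 1.18e-07, and adjusted p = 0.207 with an estimated correlation. Herpud1, which acts in degradation from the endoplasmic reticulum, rose most (log2 fold change 1.16 ± 0.043 (SE), adjusted p = 3.18e-23). Of 21 aminoacyl-tRNA synthetases, 13 rose and 2 fell (14 and 2 adjusted over the list alone), with a median log2 change of 0.20. For aminoacyl-tRNA synthetases, camera adjusted p = 3.64e-09, and adjusted p = 0.153 with an estimated correlation. Cars changed by 0.61 and Farsa by 0.46. Of 24 melanocyte and pigment genes, 18 rose and 2 fell (18 and 2 adjusted over the list alone), with a median log2 change of 0.17. For melanocyte and pigment genes, camera adjusted p = 7.12e-11, and adjusted p = 0.144 with an estimated correlation. Trpm1 rose by 0.44 and Pmel, the fibril protein of melanosomes, by 0.30, while Kit fell by 0.34.

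Of 45 ribosome biogenesis genes, 6 rose and 24 fell (6 and 25 adjusted over the list alone), with a median log2 change of -0.082. For ribosome biogenesis genes, camera adjusted p = 7.54e-05, and adjusted p = 0.362 with an estimated correlation. Bms1 changed by -0.34 and Polr1a, the largest subunit of RNA polymerase I, by -0.28. Of 24 m6A methyltransferases, demethylases and readers, 2 rose and 10 fell (2 and 10 adjusted over the list alone), with a median log2 change of -0.093. For m6A methyltransferases, demethylases and readers, camera adjusted p = 0.0311, and adjusted p = 0.291 with an estimated correlation. The demethylase gene Fto rose (log2 fold change 0.51 ± 0.031 (SE), adjusted p = 1.36e-16), and Igf2bp3 (-0.48) and Ythdc2 (-0.34) fell. Of 26 genes of G2 and mitosis, 2 rose and 10 fell (2 and 10 adjusted over the list alone), with a median log2 change of -0.045. For genes of G2 and mitosis, camera adjusted p = 0.0266, and adjusted p = 0.362 with an estimated correlation. Of 24 cholesterol biosynthesis genes, 10 rose and 1 fell (11 and 1 adjusted over the list alone), with a median log2 change of 0.10. For cholesterol biosynthesis genes, camera adjusted p = 0.0108, and adjusted p = 0.266 with an estimated correlation. Of 37 replication-dependent histones, 13 rose and 1 fell (13 and 1 adjusted over the list alone), with a median log2 change of 0.26. For replication-dependent histones, camera adjusted p = 0.029, and adjusted p = 0.291 with an estimated correlation. Hist1h2af was the 1 that fell (-1.34). Of 19 elongation factors and other TOP mRNAs, 11 rose and 4 fell (11 and 5 adjusted over the list alone), with a median log2 change of 0.067. For elongation factors and other TOP mRNAs, camera adjusted p = 0.0212, and adjusted p = 0.541 with an estimated correlation. Of 74 mitochondrial ribosomal proteins, 20 rose and 1 fell (16 and 1 adjusted over the list alone), with a median log2 change of 0.068. For mitochondrial ribosomal proteins, camera adjusted p = 0.0378, and adjusted p = 0.362 with an estimated correlation.

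Heat shock, redox and other lists did not pass as lists in input RNA, although single members did. Of 19 heat shock genes, 4 rose and 7 fell (5 and 7 adjusted over the list alone, camera adjusted p = 0.61). Their median of -0.0076, mean of 0.00032 and camera direction (lower) differ in sign. Of 26 oxidative stress and NRF2 targets, 8 rose and 7 fell (8 and 8 adjusted over the list alone, camera adjusted p = 0.824). Of 21 p53 targets, 4 rose and 7 fell (4 and 7 adjusted over the list alone, camera adjusted p = 0.437). Of 50 translation initiation factors, 14 rose and 12 fell (15 and 13 adjusted over the list alone, camera adjusted p = 0.719). Their median of 0.0034, mean of -0.0025 and camera direction (higher) differ in sign. Of 34 DNA replication genes, 3 rose and 11 fell (3 and 11 adjusted over the list alone, camera adjusted p = 0.088). Of 22 interferon and antigen presentation genes, 3 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.922). Of 29 glycolysis and hypoxia targets, 10 rose and 6 fell (10 and 7 adjusted over the list alone, camera adjusted p = 0.0835). Of 27 fatty acid metabolism genes, 7 rose and 10 fell (8 and 10 adjusted over the list alone, camera adjusted p = 0.544). Of 20 immediate early genes, 6 rose and 1 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.304). Their median of -0.026, mean of 0.084 and camera direction (higher) differ in sign. Of 35 proteasome subunits, 14 rose and 7 fell (14 and 8 adjusted over the list alone, camera adjusted p = 0.271). Of 6 fibroblast markers, 1 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.538). Postn, a matrix protein of fibroblasts, had a log2 fold change of -1.03. Markers of other cell types were scarce: the 1 measured leukocyte marker (Cd68, -0.13) and the 2 epithelial and endothelial markers (Cdh1, 0.25, and Vwf, 0.23) did not pass.

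With limma and Benjamini-Hochberg adjustment, 3803 of 10443 genes differed in input RNA (1865 higher and 1938 lower in KO). Most differences were small: 35 genes were over 2-fold higher and 36 over 2-fold lower, and the median absolute log2 fold change of called genes was 0.21. The count was 1276 without limma's trend of variance on level, 829 with input and footprint libraries fitted together and 1721 with DESeq2 on the recovered reads. None of the 14 lists that passed with a preset correlation passed with an estimated one. For these lists, the numbers of genes called in the list's direction that moved by over 1.5 times under a setting counted are given here. Without limma's trend, counts moved for unfolded protein response (18 to 10), cytosolic ribosomal proteins (56 to 17), mitochondrial ribosomal proteins (20 to 2), TOP mRNAs (11 to 0), ribosome biogenesis (24 to 5) and the m6A list (10 to 2). The same setting moved aminoacyl-tRNA synthetases (13 to 8), nuclear-encoded oxidative phosphorylation (54 to 24), histones (13 to 6), pigment genes (18 to 9), G2 and mitosis (10 to 1) and cholesterol biosynthesis (10 to 3). With DESeq2, counts moved for mitochondrial ribosomal proteins (20 to 3), ribosome biogenesis (24 to 12), the m6A list (10 to 5), histones (13 to 0), G2 and mitosis (10 to 6) and cholesterol biosynthesis (10 to 4). Without KO input replicate 1, counts moved for cholesterol biosynthesis (10 to 6). Without KO input replicate 2, counts moved for mitochondrial ribosomal proteins (20 to 8) and histones (13 to 4). With both kinds of library fitted together, counts moved for unfolded protein response (18 to 11), cytosolic ribosomal proteins (56 to 19), mitochondrial ribosomal proteins (20 to 2), TOP mRNAs (11 to 5) and ribosome biogenesis (24 to 10). The same setting moved the m6A list (10 to 1), nuclear-encoded oxidative phosphorylation (54 to 29), G2 and mitosis (10 to 4) and cholesterol biosynthesis (10 to 3).

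In footprints, which count ribosomes on each mRNA, 6 of 7 mitochondrially encoded genes and 12 of 24 pigment genes were higher in KO, and 17 of 33 stress response genes were lower. None of these lists passed with an estimated correlation (adjusted p = 0.181, 0.171 and 0.171). Of 33 integrated stress response genes, 1 rose and 17 fell (1 and 19 adjusted over the list alone), with a median log2 change of -0.23. For integrated stress response genes, camera adjusted p = 2.7e-11, and adjusted p = 0.171 with an estimated correlation. Footprints of Chac1 fell from 334 ± 24.4 to 142 ± 11.6 normalized reads (SD, n = 2; log2 fold change -1.23 ± 0.16 (SE), adjusted p = 3.84e-06). Those of the transcription factor gene Atf3 fell by 1.23 (adjusted p = 0.0143) and of Slc7a11, the cystine transporter, by 1.03 (adjusted p = 0.0138). Trib3 fell by 0.90 (adjusted p = 1.5e-06). Wars (0.26), a tryptophanyl-tRNA synthetase, was the 1 member that rose. Of 7 mitochondrially encoded genes, 6 rose and 0 fell (6 and 0 adjusted over the list alone), with a median log2 change of 0.56. For mitochondrially encoded genes, camera adjusted p = 6.35e-06, and adjusted p = 0.181 with an estimated correlation. mt-Nd4 rose by 0.75 and mt-Nd2 by 0.71. Of 24 melanocyte and pigment genes, 12 rose and 0 fell (14 and 1 adjusted over the list alone), with a median log2 change of 0.22. For melanocyte and pigment genes, camera adjusted p = 6.09e-13, and adjusted p = 0.171 with an estimated correlation. Tyrp1, an enzyme of melanin synthesis, rose (log2 fold change 0.65 ± 0.013 (SE), adjusted p = 1e-21), as did Met (0.56).

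The largest single-gene changes in footprints rested on few reads. Mfsd2a rose most (log2 fold change 2.33 ± 0.53 (SE), adjusted p = 0.00333), from 6 reads over both WT libraries to 25, and it was higher in input too. Smtnl2 (1.83, 9 to 26 reads), Gucd1 (1.78, 9 to 25) and Slc16a7 (1.76, 9 to 24) also rose. Gas2, Snrpg, Sema7a, Pcdhga3, Pisd and Parp14 rose by between 1.87 and 2.12, from at most 7 reads in WT, and edgeR's filter on low counts left them out. Pisd has 3 named pseudogene copies, with which it may share reads. Calhm2 fell most (log2 fold change -2.57 ± 0.55 (SE), adjusted p = 0.00209), from 37 reads to 5. Footprints also fell for Mgst1 (-2.16, 68 to 11 reads), Shroom1 (4-fold lower, 29 to 5) and Rab17 (-1.87, 36 to 7), which fell in input as well. Sfxn4, Sept4, Hoxb8, Efr3b, Cnbd2 and Eif5a2 fell by between 1.94 and 2.14, to at most 5 reads in KO, and were also left out by edgeR's filter.

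Of 26 unfolded protein response genes, 13 rose and 2 fell (15 and 3 adjusted over the list alone), with a median log2 change of 0.21. For unfolded protein response genes, camera adjusted p = 7.5e-07, and adjusted p = 0.171 with an estimated correlation. Sdf2l1 rose by 0.58, and the chaperone genes Calr by 0.46 and Hyou1 by 0.39. Of 19 heat shock genes, 8 rose and 1 fell (9 and 1 adjusted over the list alone), with a median log2 change of 0.15. For heat shock genes, camera adjusted p = 7.93e-05, and adjusted p = 0.181 with an estimated correlation. Dnajb1 changed by 0.60, Hsp90aa1 by 0.34 and Ahsa1 by -0.61. Of 19 elongation factors and other TOP mRNAs, 10 rose and 0 fell (12 and 1 adjusted over the list alone), with a median log2 change of 0.12. For elongation factors and other TOP mRNAs, camera adjusted p = 8.44e-09, and adjusted p = 0.171 with an estimated correlation. Pabpc1 rose by 0.55, Eef1a1 by 0.54 and Eef2 by 0.41. Of 24 cholesterol biosynthesis genes, 7 rose and 0 fell (8 and 0 adjusted over the list alone), with a median log2 change of 0.30. For cholesterol biosynthesis genes, camera adjusted p = 0.00106, and adjusted p = 0.375 with an estimated correlation. Sc5d rose by 0.60 and Sqle by 0.48. Of 29 glycolysis and hypoxia targets, 9 rose and 2 fell (9 and 2 adjusted over the list alone), with a median log2 change of 0.11. For glycolysis and hypoxia targets, camera adjusted p = 0.00257, and adjusted p = 0.368 with an estimated correlation. Hk2 changed by 0.51. Of 26 genes of G2 and mitosis, 5 rose and 0 fell (5 and 0 adjusted over the list alone), with a median log2 change of 0.12. For genes of G2 and mitosis, camera adjusted p = 0.00413, and adjusted p = 0.301 with an estimated correlation. Cenpf changed by 0.43. Of 59 cytosolic ribosomal proteins, 16 rose and 5 fell (17 and 7 adjusted over the list alone), with a median log2 change of 0.18. For cytosolic ribosomal proteins, camera adjusted p = 0.044, and adjusted p = 0.301 with an estimated correlation. Rps10 changed by 1.27, Rps7 by 1.18 and Rpl6 by -1.43. Of the 59 ribosomal protein genes, 45 have a named pseudogene copy that may share their short reads, so single values are uncertain.

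Histones and other lists did not pass as lists in footprints. Of 37 replication-dependent histones, 12 rose and 14 fell (13 and 16 adjusted over the list alone, camera adjusted p = 0.276). Their median of -0.072, mean of 0.081 and camera direction (lower) differ in sign. Of 26 oxidative stress and NRF2 targets, 2 rose and 2 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.232). Of 21 p53 targets, 0 rose and 2 fell (0 and 2 adjusted over the list alone, camera adjusted p = 0.14). Of 74 mitochondrial ribosomal proteins, 3 rose and 8 fell (3 and 8 adjusted over the list alone, camera adjusted p = 0.232). Of 50 translation initiation factors, 8 rose and 7 fell (13 and 10 adjusted over the list alone, camera adjusted p = 0.841). Of 45 ribosome biogenesis genes, 5 rose and 4 fell (6 and 4 adjusted over the list alone, camera adjusted p = 0.872). Of 24 m6A methyltransferases, demethylases and readers, 1 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.768). Of 21 aminoacyl-tRNA synthetases, 4 rose and 7 fell (4 and 7 adjusted over the list alone, camera adjusted p = 0.232). Of 71 nuclear-encoded oxidative phosphorylation genes, 6 rose and 20 fell (7 and 20 adjusted over the list alone, camera adjusted p = 0.145). Of 34 DNA replication genes, 5 rose and 6 fell (8 and 7 adjusted over the list alone, camera adjusted p = 0.841). Their median of 0.027, mean of -0.0023 and camera direction (higher) differ in sign. Of 22 interferon and antigen presentation genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.232). Of 27 fatty acid metabolism genes, 2 rose and 2 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.856). Their median of 0.028, mean of -0.033 and camera direction (higher) differ in sign. Of 20 immediate early genes, 1 rose and 5 fell (2 and 5 adjusted over the list alone, camera adjusted p = 0.144). Of 35 proteasome subunits, 4 rose and 9 fell (6 and 9 adjusted over the list alone, camera adjusted p = 0.232). Of 6 fibroblast markers, 1 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.293).

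With limma, 1309 of 10453 genes differed in footprints (659 higher and 650 lower), 40 of them over 2-fold higher and 65 over 2-fold lower. The count was 0 without limma's trend (1807 genes at an unadjusted p under 0.05), 2313 with both kinds of library fitted together, 460 with DESeq2 and 1473 with edgeR on the recovered reads. It was 807 without WT footprint replicate 1 and 788 without WT replicate 2. All 10 lists that passed had 0 genes called without the trend. Other numbers of genes called in the list's direction that moved by over 1.5 times under a setting counted are given here. With DESeq2, counts moved for stress response (17 to 9), unfolded protein response (13 to 8), TOP mRNAs (10 to 6), mitochondrially encoded genes (6 to 2) and cholesterol biosynthesis (7 to 4). Without WT footprint replicate 1, counts moved for stress response (17 to 9). Without WT footprint replicate 2, counts moved for mitochondrially encoded genes (6 to 2). With both kinds of library fitted together, counts moved for G2 and mitosis (5 to 10). Nuclear-encoded oxidative phosphorylation, which did not pass as a list, had 20 genes lower, but 10 without WT footprint replicate 1, 9 without WT replicate 2, 10 without KO replicate 1 and 8 with DESeq2.

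Translational efficiency, footprints relative to input RNA, was tested as the interaction of genotype and kind of library. It asks whether ribosome occupancy changed beyond the change in mRNA. Values were scaled over all 8 libraries, so changes are relative to the typical gene (median log2 change 0.005). A rise or fall of translation shared by most genes would not be seen. Translational efficiency was lower in KO for 26 of 33 stress response genes and 23 of 71 nuclear-encoded oxidative phosphorylation genes, and higher for 7 of 7 mitochondrially encoded genes. Of 33 integrated stress response genes, 0 rose and 26 fell (0 and 29 adjusted over the list alone), with a median log2 change of -0.78. For integrated stress response genes, camera adjusted p = 4.19e-28, and adjusted p = 0.02 with an estimated correlation. Chac1 changed most (log2 fold change -2.86 ± 0.20 (SE), adjusted p = 4.16e-05, a 7.26-fold decrease). Nupr1 (-2.08, adjusted p = 0.00711), Trib3 (-1.99, adjusted p = 2.21e-04) and Slc7a11 (-1.91, adjusted p = 0.0113) followed. Atf4 itself, named after its values were seen, changed by -0.97 (adjusted p = 1.03e-04). Its input changed by 0.39 (adjusted p = 3.34e-15) and its footprints by -0.59 (adjusted p = 8.17e-06).

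**Figure D2:**
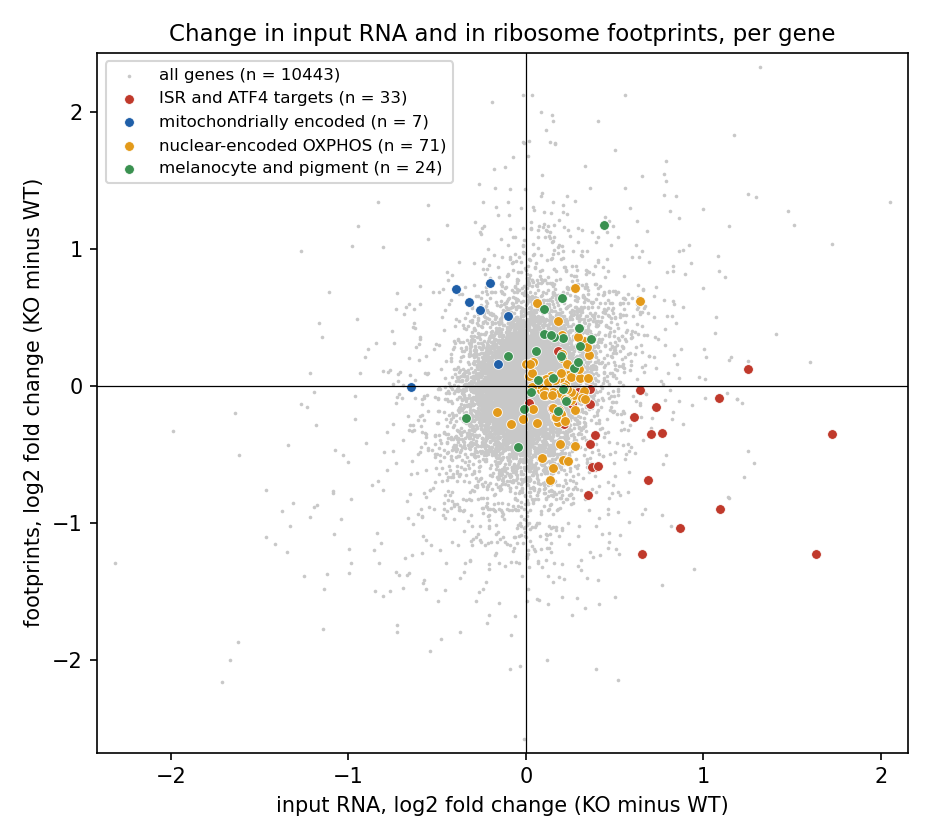
Log2 fold change (KO minus WT) of input RNA (horizontal axis) and of footprints (vertical axis) for 10443 genes (grey points) and for members of 4 fixed lists (coloured points). Of the 33 stress response genes (red), 29 were called higher in input and 17 lower in footprints, and of the 7 mitochondrially encoded genes (blue), 7 were called lower in input and 6 higher in footprints.

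Of 7 mitochondrially encoded genes, 7 rose and 0 fell (7 and 0 adjusted over the list alone), with a median log2 change of 0.82. For mitochondrially encoded genes, camera adjusted p = 5.93e-12, and adjusted p = 0.0247 with an estimated correlation. mt-Nd2 rose by 1.10 ± 0.095 and mt-Nd5 by 0.93 ± 0.060 (SE). Footprints of the list lay far below input in WT (median log2 ratio -3.65). Recovered footprint reads of mt-Nd2 were 73 and 58 in WT and 80 and 82 in KO, and of mt-Nd5 329 and 326 in WT and 372 and 388 in KO. Which ribosomes these reads come from was not tested, so the change may not compare with that of the other lists. The exception in footprints, mt-Nd6, was at -0.010 there and rose by 0.64 in translational efficiency (adjusted p = 1.28e-04). Of 71 nuclear-encoded oxidative phosphorylation genes, 0 rose and 23 fell (1 and 28 adjusted over the list alone), with a median log2 change of -0.19. For nuclear-encoded oxidative phosphorylation genes, camera adjusted p = 7.5e-12, and adjusted p = 0.0247 with an estimated correlation. Ndufa13 (-0.82) and Ndufb10 (-0.75) of complex I and the ATP synthase subunit Atp5j2 (-0.78) fell. Of 21 aminoacyl-tRNA synthetases, 0 rose and 9 fell (1 and 9 adjusted over the list alone), with a median log2 change of -0.11. For aminoacyl-tRNA synthetases, camera adjusted p = 1.36e-04, and adjusted p = 0.0625 with an estimated correlation. Cars (-0.83) and Sars (-0.78), which are also on the stress response list, and Aars (-0.52) fell. Of 19 elongation factors and other TOP mRNAs, 8 rose and 0 fell (9 and 2 adjusted over the list alone), with a median log2 change of 0.16. For elongation factors and other TOP mRNAs, camera adjusted p = 1.36e-04, and adjusted p = 0.0625 with an estimated correlation. Pabpc1 changed by 0.56 and Eef1a1 by 0.34. Of 19 heat shock genes, 6 rose and 1 fell (7 and 2 adjusted over the list alone), with a median log2 change of 0.21. For heat shock genes, camera adjusted p = 6.13e-04, and adjusted p = 0.0625 with an estimated correlation. Hsp90aa1 changed by 0.55 and Ahsa1 by -0.60. Of 26 genes of G2 and mitosis, 6 rose and 1 fell (9 and 1 adjusted over the list alone), with a median log2 change of 0.17. For genes of G2 and mitosis, camera adjusted p = 1.36e-04, and adjusted p = 0.0625 with an estimated correlation. Hmmr changed by 0.56 and Cenpf by 0.52.

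Of 24 melanocyte and pigment genes, 8 rose and 3 fell (10 and 4 adjusted over the list alone), with a median log2 change of 0.0018. For melanocyte and pigment genes, camera adjusted p = 0.0384, and adjusted p = 0.147 with an estimated correlation. Met changed by 0.46, Tyrp1 by 0.44 and Mlana by -0.34. Of 45 ribosome biogenesis genes, 10 rose and 2 fell (13 and 4 adjusted over the list alone), with a median log2 change of 0.11. For ribosome biogenesis genes, camera adjusted p = 0.00973, and adjusted p = 0.361 with an estimated correlation. Nop58 changed by 0.34. Of 37 replication-dependent histones, 3 rose and 9 fell (3 and 11 adjusted over the list alone), with a median log2 change of -0.29. For replication-dependent histones, camera adjusted p = 0.01, and adjusted p = 0.0994 with an estimated correlation. Of 74 mitochondrial ribosomal proteins, 2 rose and 6 fell (3 and 11 adjusted over the list alone), with a median log2 change of -0.059. For mitochondrial ribosomal proteins, camera adjusted p = 0.0106, and adjusted p = 0.12 with an estimated correlation. Of 20 immediate early genes, 1 rose and 4 fell (1 and 4 adjusted over the list alone), with a median log2 change of -0.18. For immediate early genes, camera adjusted p = 0.0258, and adjusted p = 0.141 with an estimated correlation. Of 35 proteasome subunits, 2 rose and 5 fell (3 and 9 adjusted over the list alone), with a median log2 change of -0.076. For proteasome subunits, camera adjusted p = 0.0446, and adjusted p = 0.361 with an estimated correlation.

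The remaining lists did not pass as lists in translational efficiency, although Herpud1 fell by 0.95 and Bax, which promotes apoptosis, by 1.03. Of 26 unfolded protein response genes, 6 rose and 3 fell (7 and 3 adjusted over the list alone, camera adjusted p = 0.401). Their median of 0.0044, mean of -0.044 and camera direction (higher) differ in sign. Of 26 oxidative stress and NRF2 targets, 3 rose and 2 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.307). Of 21 p53 targets, 0 rose and 2 fell (0 and 2 adjusted over the list alone, camera adjusted p = 0.401). Their median of 0.0064, mean of -0.12 and camera direction (lower) differ in sign. Of 59 cytosolic ribosomal proteins, 10 rose and 13 fell (12 and 17 adjusted over the list alone, camera adjusted p = 0.322). Their median of 0.022, mean of -0.014 and camera direction (lower) differ in sign. Of 50 translation initiation factors, 5 rose and 5 fell (8 and 11 adjusted over the list alone, camera adjusted p = 0.331). Of 24 m6A methyltransferases, demethylases and readers, 0 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.105). Of 34 DNA replication genes, 6 rose and 2 fell (6 and 4 adjusted over the list alone, camera adjusted p = 0.258). Of 22 interferon and antigen presentation genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.31). Of 29 glycolysis and hypoxia targets, 6 rose and 1 fell (8 and 5 adjusted over the list alone, camera adjusted p = 0.153). Of 24 cholesterol biosynthesis genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.202). Of 27 fatty acid metabolism genes, 3 rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.331). Their median of 0.025, mean of -0.015 and camera direction (higher) differ in sign. Of 6 fibroblast markers, 0 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.549).

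Among single genes, Adamts14, a collagen-processing protease, rested on the most footprint reads of the large increases in translational efficiency (log2 fold change 1.74 ± 0.27 (SE), adjusted p = 0.00359), with footprint reads going from 30 to 64. The SE of Adamts14 in footprints alone was larger (0.32), although translational efficiency adds the spread of input. Cbx7, below, likewise had an SE of 0.45 against 0.63 in footprints, where it did not pass with limma (adjusted p = 0.0891). Errors and p-values of such genes are likely too small. Snrpg (2.14), Gas2 (2.09), Pisd (1.91), Stmn1 (1.83), Zfhx2 (1.79), Spata2l (1.78), Zfp119a (1.72), Gucd1 (1.61) and Oaz2 (1.53) rose from at most 9 summed footprint reads in WT. With edgeR, Gas2, Stmn1, Zfhx2, Spata2l, Zfp119a and Oaz2 did not pass. Beside the stress response genes, the largest decreases were those of Sfxn4 (-2.66), Calhm2 (-2.56), Hoxb8 (-2.46), Tspan33 (-2.28), Glrx, a glutaredoxin (3.99-fold lower), and Cbx7 (-1.93), of which Hoxb8, Tspan33 and Cbx7 did not pass with edgeR. Calhm2 kept its input level (187 ± 11.2 in WT and 185 ± 1.22 in KO) while its footprint reads went from 37 to 5.

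**Figure D3:**
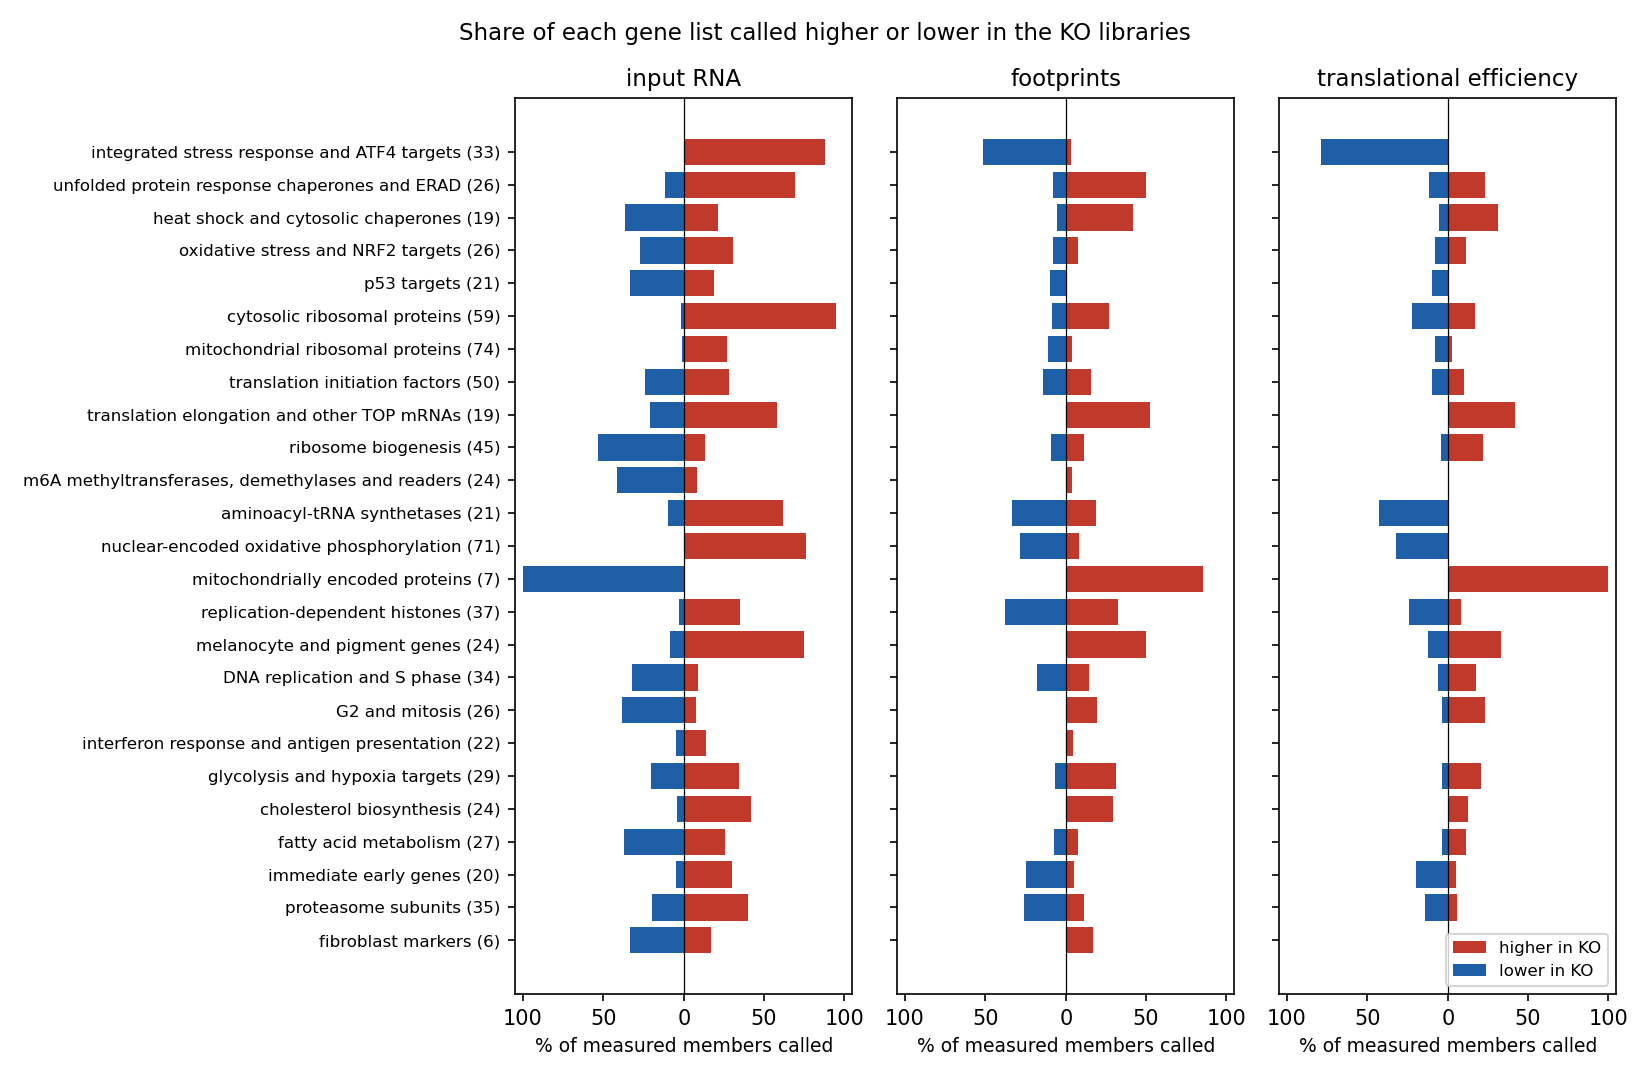
Share of the measured members of each fixed gene list (number measured in brackets) called higher (red, to the right) or lower (blue, to the left) in KO, in percent, for input RNA, footprints and translational efficiency. The stress response list had 29 of 33 higher in input and 26 of 33 lower in translational efficiency, and the mitochondrially encoded list 7 of 7 lower in input and 7 of 7 higher in translational efficiency.

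With limma's interaction test, 1021 of 10443 genes differed in translational efficiency (534 higher and 487 lower), 104 of them over 1.5-fold higher and 184 over 1.5-fold lower. The authors' deposited table lists 1023 genes with an adjusted p below 0.05, and calls 94 Up and 183 Down. The count by limma was 133 without the trend (48 higher and 85 lower), 446, 431, 419 and 431 without WT input replicate 1, WT input replicate 2, KO input replicate 1 and KO input replicate 2, and 1719 and 1675 without KO footprint replicates 1 and 2. With any library left out, between 22 and 27 stress response genes were called lower and 0 higher. In the 13 lists that passed, the numbers of genes called in the list's direction that moved by over 1.5 times under a setting counted are given here. Without limma's trend, counts moved for stress response (26 to 13), heat shock (6 to 1), mitochondrial ribosomal proteins (6 to 0), TOP mRNAs (8 to 1), ribosome biogenesis (10 to 0) and aminoacyl-tRNA synthetases (9 to 3). The same setting moved nuclear-encoded oxidative phosphorylation (23 to 5), histones (9 to 4), pigment genes (8 to 1), G2 and mitosis (6 to 1), immediate early genes (4 to 1) and proteasome subunits (5 to 0). With edgeR, counts moved for mitochondrial ribosomal proteins (6 to 15) and proteasome subunits (5 to 8). Without WT input replicate 1, counts moved for ribosome biogenesis (10 to 4), immediate early genes (4 to 2) and proteasome subunits (5 to 1). Without WT input replicate 2, counts moved for ribosome biogenesis (10 to 4), immediate early genes (4 to 2) and proteasome subunits (5 to 1). Without KO input replicate 1, counts moved for mitochondrial ribosomal proteins (6 to 3), ribosome biogenesis (10 to 3), immediate early genes (4 to 2) and proteasome subunits (5 to 1). Without KO input replicate 2, counts moved for mitochondrial ribosomal proteins (6 to 3), ribosome biogenesis (10 to 5), immediate early genes (4 to 2) and proteasome subunits (5 to 1). Without WT footprint replicate 1, counts moved for histones (9 to 4) and proteasome subunits (5 to 3). Without WT footprint replicate 2, counts moved for histones (9 to 5) and proteasome subunits (5 to 3). Without KO footprint replicate 1, counts moved for mitochondrial ribosomal proteins (6 to 10), ribosome biogenesis (10 to 17) and immediate early genes (4 to 7). Without KO footprint replicate 2, counts moved for mitochondrial ribosomal proteins (6 to 10).

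Set side by side over 10443 genes, changes in input and in footprints were only loosely related (Spearman's rho 0.166 across genes, which are not independent replicates, with -0.000446 in simulated libraries without changes). 313 genes rose in both, where independent lists would share 118, and 204 fell in both, where independent lists would share 121. Genes that rose in both included Id3 (footprints 1.17, adjusted p = 1.79e-04), Cdh13 (1.38, adjusted p = 9.78e-09) and Bcan (1.27, adjusted p = 0.0031), and Capn6 fell in both (footprints -1.15, adjusted p = 6.96e-11). Opposite calls were about as frequent as for independent lists: 125 genes were higher in input and lower in footprints against 116, and 108 lower in input and higher in footprints against 122. The change in input and in translational efficiency had a rho of -0.37 against -0.317 simulated without changes, since both use the input libraries, and a covariance of -0.0361 against -0.0121.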

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

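The tests of explanations in this part were chosen after the result was seen. The lists below had changes between genotypes in opposite directions in input RNA and in footprints, each called with the preset correlation, and an interaction test of the difference that passed. None of the single changes passed with an estimated correlation (adjusted p = 0.142 in input and 0.171 in footprints for stress response, 0.266 and 0.181 for mitochondrially encoded, 0.362 and 0.301 for G2 and mitosis). With fry, adjusted p was 0.00424 in input and 0.0362 in footprints for stress response and 0.014 and 0.0326 for mitochondrially encoded. For G2 and mitosis, fry gave 0.0489 in input and 0.0703 in footprints, which did not pass. Unlike camera, fry asks whether a list changed, not whether it changed more than other genes. The integrated stress response list had a median log2 change of translational efficiency of -0.78, the mitochondrially encoded list of 0.82, and the list of G2 and mitosis of 0.17. For the last of these the interaction passed with the preset correlation (adjusted p = 1.36e-04) and not with an estimated one (adjusted p = 0.0625). Of 125 genes called higher in input and lower in footprints, 121 passed the interaction test, and of 108 called lower in input and higher in footprints, 107 did. Passing was all but fixed by how these genes were picked, from the same libraries, and their numbers were about those of independent lists (116 and 122). No explanation, biological or technical, was tested for the mitochondrially encoded list, the list of G2 and mitosis or these genes.

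Of the 33 stress response genes, 29 were called higher in KO input and 17 lower in KO footprints (9 with DESeq2, 9 without WT footprint replicate 1 and 0 without limma's trend), and as a list only the interaction passed with an estimated correlation (adjusted p = 0.142 in input, 0.171 in footprints and 0.02 for the interaction). The interaction uses all 8 libraries and so has more residual degrees of freedom, and this contrast does not by itself mark stronger evidence. In input the list's estimated correlation was -0.00926, below the preset 0.01, and for the interaction it was 0.0322. Scaling of the libraries, which moves all genes alike, is argued against by the list's median change of translational efficiency, lower by 0.81 than the median of 10000 random lists of matched level (difference -0.81, with the lowest of those lists at -0.25), and low read numbers by the median of -0.71 over the 24 members with a mean of at least 100 footprint reads, of which 22 were called lower. A candidate explanation that stays open is that input and footprints of a genotype came from cultures in different stress states. Across the 33 genes, a larger rise in input tended to go with a larger fall in footprints (Spearman's rho -0.405 across genes, permutation p = 0.021), while over all genes rho was 0.166. The rho was weaker over the 24 better covered genes (-0.304) and without Nupr1 and Chac1 (-0.332), and no permutation test was run on these values. Genes of a list are not independent replicates, although the permutation treats them so. In normalized reads, the list's footprints lay above input in WT by a median log2 ratio of 1.56, above all 10000 random lists of matched level (percentile 100), and in KO by 0.36 (percentile 79.9). A change of translation that follows the genotype, which the design names, stays open as well and was not separated from it, since the labels tie no input library to a footprint library of the same cells.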

How the results depend on the processing

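Counts of calls moved with the test used. Alternatives on the recovered reads and a minimum of 20 reads in every library were chosen after seeing the data. In input RNA, 3803 genes (1865 higher, 1938 lower) became 1276 (633 and 643) with limma without the trend, 829 (443 and 386) with input and footprint libraries fitted together and 1721 (815 and 906) with DESeq2 on the recovered reads. In footprints, 1309 (659 and 650) became 0 (0 and 0) without the trend, with 1807 genes at an unadjusted p under 0.05, 2313 (1210 and 1103) with both kinds fitted together, 460 (236 and 224) with DESeq2, and stood at 1473 with edgeR. In translational efficiency, 1021 (534 and 487) became 133 (48 and 85) without the trend, which moved the share of higher calls from 52.3% to 36.1%. No other setting moved a count by over 1.5 times except leaving out a library. Fitting both kinds together gives each gene 1 variance, while the median SE of each kind fitted alone was 0.0595 in input and 0.169 in footprints. Such pooling raises errors in input and lowers them in footprints, the directions in which these counts moved. The cause of the other changes was not tested. With centred values the median log2 fold change of all genes was -0.00264 in input, -0.00785 in footprints and 0.00522 in translational efficiency.

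With each library left out in turn, a lone library is assumed to vary like the other groups. Counts then ran from 2858 to 3444 in input (higher 1344 to 1698, lower 1475 to 1746), from 788 to 1391 in footprints (higher 431 to 683, lower 350 to 742) and from 419 to 1719 in translational efficiency (higher 195 to 850, lower 215 to 869). The libraries that moved a count by over 1.5 times were WT footprint replicates 1 (807) and 2 (788) for footprints. For translational efficiency they were WT input replicates 1 (446) and 2 (431), KO input replicates 1 (419) and 2 (431), and KO footprint replicates 1 (1719) and 2 (1675). Lists called ran from 9 (without WT input replicate 2) to 12 in input against 14, from 9 to 10 in footprints against 10, and from 9 to 13 in translational efficiency against 13. With an estimated correlation, 0 lists passed in input, 0 in footprints and 3 in translational efficiency (stress response, mitochondrially encoded and nuclear-encoded oxidative phosphorylation). The fit of translational efficiency has more residual degrees of freedom than those of input or footprints alone. With fry, 13 lists passed in input, 5 in footprints and 20 in translational efficiency. Without WT footprint replicate 2, 2 of the 7 mitochondrially encoded genes rose in footprints against 6, and 9 stress response genes fell without WT footprint replicate 1 against 17.

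The replicate numbers are not known to pair the libraries. Deviations from the group mean of libraries with the same number correlated between -0.00899 and 0.00661 across 8869 genes. These deviations were mostly counting noise (chi-square over degrees of freedom between 1.1 and 1.22), which is independent between libraries. Values near 0 therefore do not tell whether the numbers pair the libraries. With the replicate number as a block, 3877 genes were called in input, 1548 in footprints and 938 in translational efficiency, and 11, 9 and 13 lists.

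Directions that turned all belonged to results that did not pass the test. For lists the values are medians, and it was the direction of the test that turned. In input RNA, fry turned oxidative stress and NRF2 targets (0.0279) and the interferon list (-0.0443). The interferon list turned with a mean of at least 5 (-0.00873) and without WT input replicate 2 (0.0201), against -0.0736 without replicate 1. The NRF2 list turned without KO input replicate 1 (0.0178), and ran from -0.00299 without WT input replicate 1 to 0.0355 without replicate 2. Vwf ran from -0.41 without WT input replicate 1 to 0.87 without replicate 2. Hist1h4b ran from -0.0057 without KO input replicate 2 to 0.15 without replicate 1.

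In footprints, fry turned histones (-0.0724) and DNA replication (0.027). The replicate block turned ribosome biogenesis (0.00833) and fatty acid metabolism (0.0279), and centred values turned ribosome biogenesis (-0.00424). Ribosome biogenesis also turned without WT footprint replicate 1 (-0.0222) and KO replicate 2 (-0.0302), against 0.033 without WT replicate 2. Fatty acid metabolism turned without WT footprint replicate 1 (0.00959) and KO replicate 1 (0.005), against 0.0448 without KO replicate 2. Mettl5 ran from -0.029 without WT footprint replicate 1 to 0.27 without replicate 2. Without KO footprint replicate 1, mt-Nd6 was at 0.039 and the m6A list at -0.0289, against -0.060 and 0.0837 without replicate 2. DNA replication was at -0.00817 without KO footprint replicate 2 and 0.0493 without replicate 1. In translational efficiency, fry turned the unfolded protein response list (0.00439). Vwf was at -0.15 without WT input replicate 2, -0.084 without WT footprint replicate 2 and 1.14 without WT input replicate 1. Cdh1 was at -0.058 without KO footprint replicate 2 and 0.53 without replicate 1. Across genes, the rho of input and footprints was 0.171 with a mean of at least 5 and 0.165 with a pseudocount of 0.1.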

Other observations

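The test of pseudogene copies in this part was set before its result was seen, and the other tests after. Beyond the comparison of genotypes, gene groups differed widely in footprints relative to input within WT. Ratios here are those of normalized reads, scaled over both kinds of library, so they are relative to the typical gene and not ratios of reads. The median log2 ratio was 0.0107 over genes without a named pseudogene copy outside the ribosomal protein and histone lists. Beside stress response genes and replication-dependent histones, given elsewhere, the median log2 ratio was 1.27 for aminoacyl-tRNA synthetases, 1.10 for nuclear-encoded oxidative phosphorylation, 1.02 for proteasome subunits, 1.04 for glycolysis and hypoxia targets, 0.915 for interferon and antigen presentation and 0.578 for mitochondrial ribosomal proteins, each above at least 99.8% of 10000 random lists of matched level. It was -3.65 for the mitochondrially encoded genes and -0.39 for elongation factors and other TOP mRNAs, at percentiles 0 and 0.07. On this scale, footprints exceeded input in WT 12.5-fold for the stress response gene Chac1, 20.9-fold for Trib3 and 19.5-fold for Ddit4, and in KO 1.67-fold, 5.16-fold and 9-fold. These are high members: the list's median in WT was 2.94-fold. Atf4 lay below input in WT (1278 and 1251 in input, 1026 and 1147 in footprints). As recovered reads, Chac1 in WT had 64 and 58 in input and 166 and 138 in footprints.

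Footprints of replication-dependent histones went both ways between genotypes, with 12 genes higher and 14 lower in KO. The H2B genes Hist1h2bh (1.54, adjusted p = 1.04e-09) and Hist1h2bk (1.49, adjusted p = 1.01e-08) rose in KO, while the H4 genes Hist1h4b (-0.68, adjusted p = 1.03e-10) and Hist1h4d (-0.57, adjusted p = 1.79e-17) fell. In input, Hist1h2bk (0.79, adjusted p = 0.0175) and Hist1h4d (0.37, adjusted p = 0.00241) rose. Hist1h2bh did not pass there, at 0.091 (adjusted p = 0.717) and nor did Hist1h4b, at 0.070 (adjusted p = 0.794). Reads of near-identical copies could be assigned to the wrong member of a family, so the values are uncertain, and the high ratio of the H1 genes (median 5.89, below) speaks only to the level.

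Replication-dependent histones lay far above input in WT footprints (median log2 ratio 6.17, 72.1-fold). Reads shared between near-identical copies as the whole reason are argued against by the 4 linker histone H1 genes, whose sequences differ more and whose median log2 ratio was 5.89. Their values were spread widely: 3.75 for Hist1h1c, 4.2 for Hist1h1e, 7.57 for Hist1h1t and 7.98 for Hist1h1d. H1 genes may still share reads with one another, which was not tested. The value needed by selection of polyadenylated RNA for the input was there: the 6 measured replication-independent histones, whose mRNAs carry a poly(A) tail, had a median of -0.769, lower by 6.94. That selection, which 1 of the labels names, is a candidate explanation. No biological explanation was tested.

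Ribosomal protein genes lay far below input in WT footprints (median log2 ratio -3.42), as did Gapdh (154-fold). Low translation of TOP mRNAs as the whole reason is argued against by 16 other TOP mRNAs without a named pseudogene copy, with a median of -0.102. A part is not excluded: all 19 other TOP mRNAs had a median of -0.39, where random lists of matched level had 0.65. Footprints lost on genes with pseudogene copies, where short reads match several places, may explain it: outside the ribosomal protein and histone lists, 199 genes with a RefSeq copy named after them had a median lower by 1.59 than the others (difference -1.59, permutation p = 1e-04, the smallest that 10000 draws can give), and -1.57 against the 100 genes of nearest input level, a check added after the first result was seen. Within the list, 45 of 59 genes had a named copy, with a median of -3.86 against -0.944 for the rest. Changes of these genes between genotypes compare the same genes, and how reads with several matches were handled is not given in the sources used here.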
